A study of Mus musculus with 8 samples.

How the data were processed

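Polyadenylated RNA of 8 samples of bone-marrow-derived macrophages was sequenced. Per the labels' protocols, macrophages were grown from C57BL/6 bone marrow with 20 ng of recombinant M-CSF for 7 days and treated with 1 µg/ml of LPS, RNA was isolated by column, and libraries were made from 220 ng of total RNA with a stranded mRNA kit and sequenced on a NextSeq 500. The deposited table holds whole-number counts per gene that the authors made from the reads, with Entrez identifiers, symbols and gene lengths, for 17823 genes. The submitters' processing notes name STAR and the mm10 genome. The version of STAR, the counting tool, the gene annotation and the strand setting are not given in the sources used here, so overlapping and antisense genes, and genes with near-identical copies, are uncertain. Columns were matched to samples by the identifier in each sample's description. The table holds 8 genes without a symbol, which carry an Entrez identifier.

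Groups were taken from the sample titles: 4 tdT-positive and 4 tdT-negative libraries, called biological replicates in the labels. No label says whether a replicate number marks a shared mouse, culture or day, so p-values measure the spread between these samples. No library was a repeat of another: the chi-square per degree of freedom between the counts of libraries of a group lay between 54.0 and 759, over genes with at least 20 counts.

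Genes were kept by the default expression filter of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 12610. Counts were scaled by trimmed mean of M values (TMM factors 0.865 to 1.15) and compared with the quasi-likelihood test of edgeR with the group as the only term, as fixed before the data were examined, together with the gene lists, the rule for named genes and the alternative settings listed first. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The fit with the replicate number as a block was among those settings. The replicate numbers are shared between groups in the titles. Deviations from the group means of log2 CPM (counts scaled to the same library size) were correlated between libraries of the same number by 0.63, 0.28, 0.62 and 0.56 for numbers 1 to 4, all above 0.1, and every library correlated best with the library of its own number in the other group, so values of the blocked fit are printed where they change a call.

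Lists of genes, 36 in all, were tested with camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, which tests whether the genes of a list move on balance in a single direction without comparing them with other genes. The 36 lists cover LPS-response cytokines, chemokines and effectors, interferon, oxidant, stress, lipid and metabolic genes, the cell cycle, macrophage identity, the surroundings of Il19, and markers of other blood, stromal and osteoclast cells. The text names Il19 and its neighbours, the 10 genes with the largest rises and falls among those passing with a mean log2 CPM of at least 2 and no overlap between the groups, up to 4 members with the smallest p of each list that was called or had at least 3 members passing, and the most abundant member of each list of other cell types. The parts of that rule on the largest changes and on list members were applied to the blocked fit after the data had been seen. Il12b, Ccl17, Cxcl3, Ptger4, S100a8, Csf3r, Ebf1, Cflar, Traf1, Irf8, Cd274 and Dpep1 are named outside the rule, after their values were seen, because they are among the few members of a list or fit that passed. Some genes that the rule names or that passed are not reported here.

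On data simulated from these libraries with 200 changed genes, the unblocked edgeR fit recovered 0% of genes changed by a log2 fold of 0.5, 61.2% at 1 and 97.0% at 2, and the blocked fit 73.1%, 97.0% and 100%, with 0 and 25 false calls among 12307 unchanged genes. Beside its 25 false calls, the blocked fit recovered 49, 65 and 66 genes changed by a log2 fold of 0.5, 1 and 2. In this simulation, false calls thus made up a larger share of its calls than the threshold on the adjusted p aims at. The simulation used gene means that vary by replicate number and the dispersions of the blocked fit. The advantage of that fit was therefore built in. Changed genes were drawn from those with a mean log2 CPM of at least 2, so recovery of lower genes was not measured.

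Alternatives were DESeq2 1.42.0 size factors, library totals and upper-quartile factors in place of TMM, the replicate block, the DESeq2 Wald test, limma voom, no filter and a stricter filter (1 CPM in at least 4 libraries), thresholds of 0.01 and 0.1, a test against a 1.5-fold change, and leaving out each library. Those on the blocked fit, including a correction for gene length and GC content and the Il10 family list without Il19, were added after the data had been seen. The correction subtracted from each library a lowess trend (span 0.4) on gene length and then on GC content, the latter from GENCODE vM21 transcripts (GRCm38, the mm10 assembly) matched by Entrez identifier to 16209 of 17823 genes (90.9%). Coordinates are from the same annotation and count from 1. R 4.3.3, Python 3.11.15, SciPy 1.17.1 and matplotlib 3.10.9 were used.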

Results

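RNA sequencing was carried out on macrophages grown from bone marrow of C57BL/6 mice with M-CSF for 7 days and treated with 1 µg/ml of lipopolysaccharide (LPS), a component of the bacterial outer membrane that activates macrophages through Toll-like receptor 4. The cells carried a tdTomato (tdT) reporter of Il19, an Il10-family cytokine gene, and the libraries fall into a tdT-positive and a tdT-negative group. Each group has 4 libraries, called biological replicates in the labels and numbered 1 to 4 in both groups. The 8 libraries hold between 49850537 and 58516454 counts over genes. At these depths a count of 3 corresponds to between 0.0490 and 0.0696 CPM in a single library. The comparison asks how macrophages that express the Il19 reporter differ from those that do not. How the positive and negative cells were separated is not given in the sources used here. Library-size-normalised CPM values are given as mean ± SD with n = 4 per group, and log2 fold changes are tdT positive over tdT negative with their standard error (SE).

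tdT-positive macrophages had 15.4 times as much Il19 transcript and 2.14 times as much Il10, the anti-inflammatory cytokine gene next to Il19 on chromosome 1. They also had more Il1f6 and Il1f9, ligands of the interleukin-36 receptor, and more of several antimicrobial and oxidant-defence genes. The tdT-negative libraries held much higher levels of collagen and other stromal genes, of the neutrophil genes S100a9, Ngp and Ltf, and of the monocyte genes Plac8, Chil3 and Ly6c2. S100a8, Lcn2, Mmp8 and Csf3r, from the same list of neutrophil markers, were higher in the tdT-positive libraries, where they were abundant. Lcn2 is also in the list of LPS effector and antimicrobial genes. Some cell-cycle and oxidative phosphorylation genes were lower in the tdT-positive libraries as well. Of the genes named in this summary, only Il19 and Plac8 passed an adjusted p under 0.05 without the replicate number in the model. The other differences rest on the fit with the replicate number as a block. The median of the antimicrobial list and the number of oxidant-defence genes that passed also depended on the scaling, as given below.

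Il19 (Entrez 329244) lies on chromosome 1 at positions 130932656 to 130940115 of GRCm38, on the minus strand. It reached 185 ± 36.6 CPM in the tdT-positive libraries and 12 ± 3.45 CPM in the tdT-negative ones. The deposited counts were 9563, 8447, 7616 and 14306 in tdT-positive replicates 1 to 4, against 561, 546, 943 and 670 in the tdT-negative replicates of the same numbers. The log2 fold change was 3.95 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000594), and Il19 was higher in 4 of 4 numbers, by 10.4 to 20.7 times. An exact two-sided permutation test of the CPM values gave p = 0.0286, the smallest value that 70 splits allow. Il10 (chromosome 1, 131019845 to 131024974) had 80.0 ± 33.6 CPM in tdT-positive and 37.3 ± 14.4 CPM in tdT-negative libraries. Its groups overlapped, and the exact permutation test gave p = 0.114, but it was higher in 4 of 4 numbers and rose by a log2 fold change of 1.09 (SE 0.09, adjusted p = 0.00455) when the replicate number was a block. Il20 and Il24, the other Il10-family genes beside Il19, had 9 and 3 counts and 2 and 0 counts in total over the tdT-positive and tdT-negative libraries, too few to compare.

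**Figure D1:**
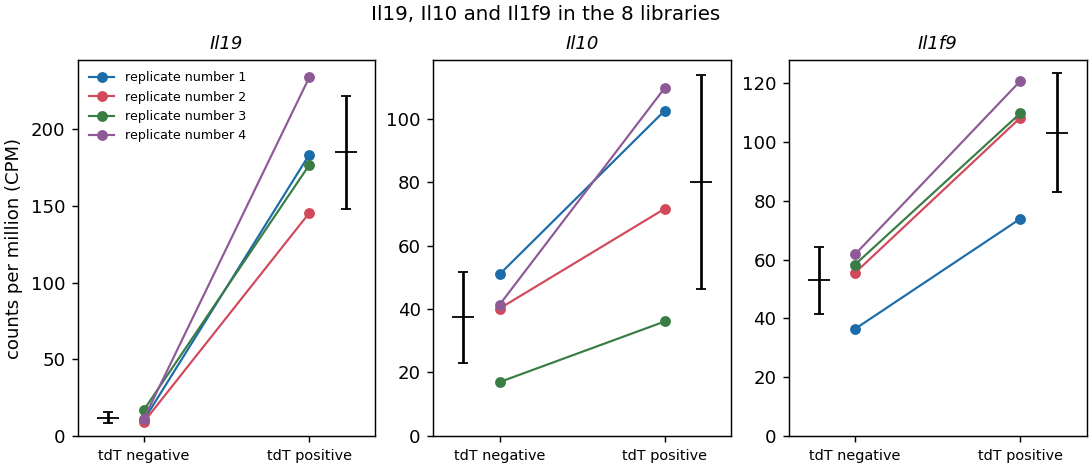
CPM of Il19, Il10 and Il1f9 on the vertical axes, with a point for each of the 8 libraries, lines joining libraries with the same replicate number, and black bars for the mean and SD of each group (n = 4). Il19 lies between 145 and 234 CPM in the tdT-positive libraries and between 9.17 and 17.0 CPM in the tdT-negative ones, and all 3 genes are higher in the tdT-positive library of each number.

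Without the replicate number in the model, 3 of 12610 genes tested passed an adjusted p under 0.05: Il19 was higher, and Plac8 and Dpep1 were lower. Libraries with the same number varied together, and with the number as a block 1998 genes passed, 1013 higher and 985 lower in the tdT-positive libraries, including those 3. Of the 1998, 1993 moved in the same direction in all 4 numbers. The fit that chose these genes used the same 4 pairs and favours such genes, so this count is no separate evidence. The lower genes changed more: the median log2 fold change was -1.16 among them and 0.38 among the higher ones, and 516 lower against 66 higher genes changed over 2-fold. All changes described from here on are from the fit with the block, unless the text says otherwise. Plac8, a gene of monocytes and progenitors, was at 0.494 ± 0.155 CPM in tdT-positive and 6.87 ± 1.56 CPM in tdT-negative libraries (log2 fold change -3.80, SE 0.29, adjusted p = 0.00359). Dpep1, a membrane dipeptidase gene, was at 0.0281 ± 0.0101 and 0.551 ± 0.218 CPM. Removing the counts of Rn45s and Lars2, which were high in tdT-positive replicate 3, left 2005 genes, 1998 of them the same. Scaling by library totals alone gave 1418 genes, of which 29.8% were higher, against 50.7% under the reported scaling. With both libraries of a number left out, the count was 1023 without number 1, 347 without number 2, 355 without number 3 and 2535 without number 4. Of 107 genes chosen by the naming rule that passed, 71, 38, 33 and 99 also passed without numbers 1, 2, 3 and 4.

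Stromal and fibroblast genes were lower in the tdT-positive libraries. Of 15 members tested, 12 fell and 3 did not pass, and adjusted over the list alone 12 fell and 1 rose. Col1a1, which encodes a chain of type I collagen, was at 32.4 ± 15.8 CPM in tdT-positive and 320 ± 361 CPM in tdT-negative libraries (log2 fold change -2.80, SE 0.50). tdT-negative replicate 4 held 857 CPM of it and the next highest 186 CPM. Its log2 fold change was -2.18 without number 4, and it did not pass without number 2 (adjusted p = 0.0540) or number 3 (adjusted p = 0.0804). Without the block it was -3.30, or -2.12 without tdT-negative replicate 4. Col3a1, Sparc and Tagln fell by 3.22, 3.08 and 3.05 on the log2 scale, and Acta2, the smooth muscle actin gene, fell by 2.70. The list was called with a preset inter-gene correlation (camera, adjusted p = 2.51e-07), and not otherwise (adjusted p = 0.612 with an estimated correlation). The difference was present in every number, with a median log2 difference from -1.68 in number 1 to -4.33 in number 4. Without number 2, 7 of the 15 members passed, and without number 3 only 1 did, with a median of -2.65 and a camera adjusted p of 7.05e-06 (adjusted p = 0.680 with an estimated correlation), and without number 4 the median was -2.26. Among genes with a mean log2 CPM of at least 2 and no overlap between the groups, those with the largest falls included Fermt2 (-3.58), Ctgf (-3.50), Col6a3 (-3.38), Wnt5a (-3.37) and Col6a2 (-3.36), which averaged 0.537 to 6.60 CPM in the tdT-positive libraries.

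Genes of the neutrophil list went both ways, and several monocyte genes were lower in the tdT-positive libraries. S100a9, a calcium-binding protein gene abundant in neutrophils, was at 0.713 ± 0.677 CPM in tdT-positive and 102 ± 71.0 CPM in tdT-negative libraries (log2 fold change -6.57, SE 1.03, adjusted p = 0.0115). Ngp and Ltf, which encode granule proteins, fell by 5.82 and 5.54. Without number 2 these 3 genes did not pass (adjusted p = 0.0766, 0.105 and 0.134), nor without number 3 (0.0613, 0.0851 and 0.0911), and Ngp and Ltf also not without number 1 (0.0564 and 0.0675). Prtn3, a serine protease gene of early granulocytes, had 0 counts in the tdT-positive libraries and 150 in the tdT-negative ones, so that it was at least 46.3-fold lower against a floor of 3 counts over the group. Of the 10 neutrophil markers tested, 4 fell, 4 rose and 2 did not pass (4 higher and 5 lower adjusted over the list alone). S100a8, Lcn2, Mmp8 and Csf3r rose, by log2 fold changes of 1.14, 0.73, 1.02 and 0.33, and were at 452, 3306, 38.2 and 171 CPM in the tdT-positive libraries. At such levels beside 0.713 CPM of S100a9, their rise does not measure RNA of neutrophils. Lcn2 is also counted below among the LPS effector and antimicrobial genes. Camera did not call the list (adjusted p = 0.404), but called it as lower without number 4 (adjusted p = 0.0447, and adjusted p = 0.697 with an estimated correlation), and no member passed without number 2. In number 4 its median log2 difference was 0.34, against -1.15, -1.98 and -1.77 in numbers 1, 2 and 3, and tdT-negative replicate 4 had 7.55 CPM of S100a9 against 87.5 to 166 CPM in the other tdT-negative libraries. Of 13 monocyte markers, 6 fell and 7 did not pass (8 lower and 1 higher adjusted over the list alone; camera, adjusted p = 0.00228, and adjusted p = 0.612 with an estimated correlation), and 2 fell without number 3. Those that fell include Chil3 (-6.58, SE 0.70), Ly6c2 (-4.35, SE 0.59) and S100a4 (-0.67, SE 0.09). Chil3 and Ly6c2 have near-identical relatives and their counts are uncertain for that reason.

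**Figure D2:**
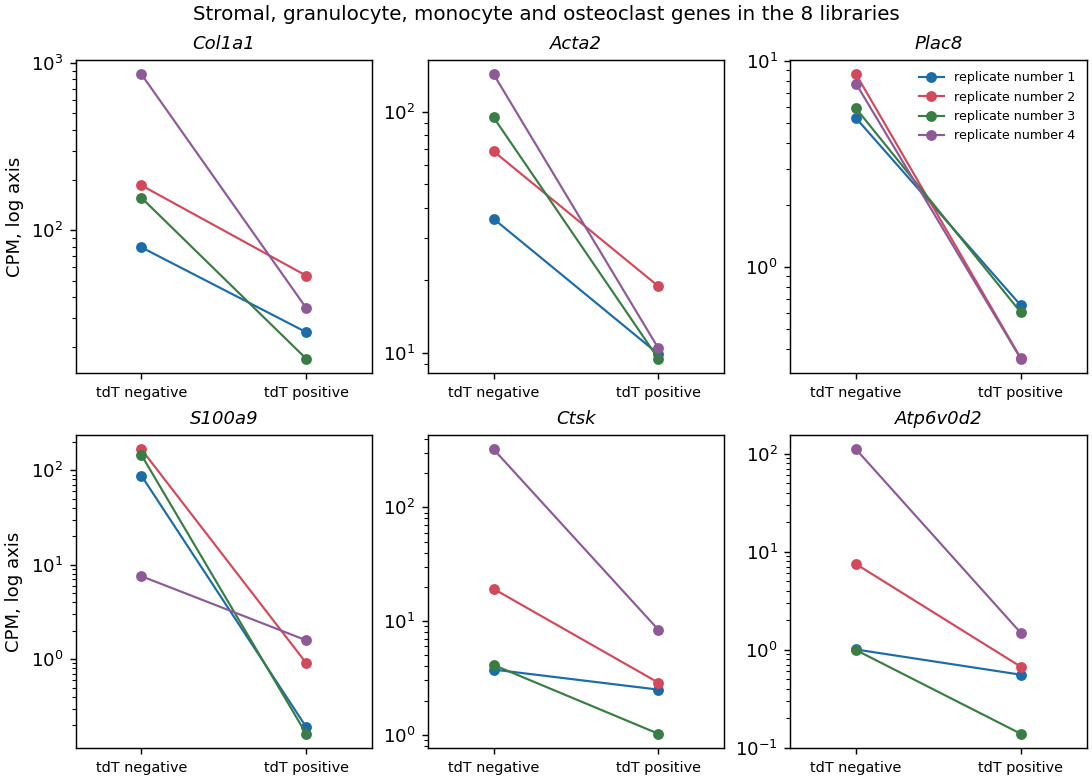
CPM on a log axis for the stromal genes Col1a1 and Acta2, the monocyte gene Plac8, the neutrophil gene S100a9 and the osteoclast genes Ctsk and Atp6v0d2, with a point for each of the 8 libraries and lines joining libraries with the same replicate number. tdT-negative replicate 4 has the most Col1a1 (857 CPM) and Ctsk (324 CPM) and the least S100a9 of the tdT-negative libraries (7.55 CPM).

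Some genes of osteoclasts and of cell fusion were also lower, by most in number 4. Of 13 tested, 4 fell and 9 did not pass (4 lower adjusted over the list alone; camera, adjusted p = 0.00228, and adjusted p = 0.631 with an estimated correlation). Ctsk, the cathepsin that degrades bone collagen, fell by 2.96 (SE 0.74), Atp6v0d2 by 4.20, Dcstamp by 2.58 and Itgb3 by 2.49. tdT-negative replicate 4 held 324 CPM of Ctsk and 110 CPM of Atp6v0d2, whereas the next highest tdT-negative library had 19.2 and 7.46 CPM. The median log2 difference of the list was -2.97 in number 4 and between -0.41 and 0.02 in the others. Without number 4 its median was -0.28, 6 members fell and camera still called it (adjusted p = 0.0277, and adjusted p = 0.697 with an estimated correlation), whereas without number 2 or number 3 no member passed.

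A few markers of further cell types were lower, and most did not pass. Among 8 haematopoietic progenitor markers only Sox4 passed and fell (-2.66, SE 0.33), with 5 lower adjusted over the list alone (camera, adjusted p = 0.0160, and adjusted p = 0.612 with an estimated correlation). Without number 4 that call was lost (adjusted p = 0.128). Of 9 dendritic cell markers, 3 fell, Fscn1 (-1.94), Ccr7 (-1.75) and Cd24a (-0.91), as many as adjusted over the list alone, and 1 fell without number 1, 2 or 3. Camera called this list without the block (adjusted p = 0.0301) and not with it (adjusted p = 0.0643, or 0.00445 without number 4), and not with an estimated correlation (adjusted p = 0.396 without the block, and 0.697 with it and without number 4). The most abundant members of the other cell type lists were measured at these levels: Blnk (B cells) averaged 138 and 139 CPM in tdT-positive and tdT-negative libraries, Pf4 (megakaryocytes) 398 and 386 CPM, Vcan (monocytes) 257 and 238 CPM, Cd48 (progenitors) 153 and 159 CPM, and Il7r (lymphocytes) 17.6 and 16.3 CPM. Ccr3 (eosinophils) averaged 40.8 and 48.2 CPM, and Hdc (mast cells and basophils) 59.2 and 72.1 CPM. Of these, Hdc fell (-0.27, SE 0.06, adjusted p = 0.0308) and the others did not pass. The cell type in brackets names the list a gene came from, and the level of a single gene does not measure RNA of that cell type. Most other members were below the filter in several lists, with 3 of 12 B cell, 4 of 14 erythroid and megakaryocyte, and 2 of 14 T and NK cell members tested. Of the 2 to 4 members tested in each of the eosinophil, mast cell and basophil, B cell, T and NK cell, and erythroid and megakaryocyte lists, Hdc and the B cell gene Ebf1 (-3.39, SE 0.57, 0.0829 and 0.980 CPM) were the only ones to pass. Adjusted over the list alone, 2 mast cell and basophil members and 1 B cell member fell and none of the other 3 lists' did, and camera called none of the 5 lists (adjusted p between 0.162 and 0.995).

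After Il19, the largest rises among genes with a mean log2 CPM of at least 2 and no overlap between the groups were those of Il1f6, Prokr1, Gdap10, Fcrlb and Rnf183. Il1f6 had 62.4 ± 22.7 CPM in tdT-positive and 24.4 ± 3.01 CPM in tdT-negative libraries (log2 fold change 1.30, SE 0.18, adjusted p = 0.00955). Il1f9 had 103 ± 20.3 and 53 ± 11.4 CPM (log2 fold change 0.97, SE 0.05, adjusted p = 0.00106). Prokr1, a prokineticin receptor gene, rose by 1.18, Gdap10 by 1.12, Fcrlb by 1.10 and Rnf183 by 1.03, and Adam33, Rabgap1l and Sap25 by 0.93 to 1.01. For all of these genes the 4 tdT-positive libraries lay above the 4 tdT-negative ones, and without the block their adjusted p lay between 0.0562 and 0.0890. Adam33 and Sap25 did not pass without number 1 (adjusted p = 0.101 and 0.0796) or without number 2 (0.113 and 0.114).

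Of the 10 tested members of the list of Il19's neighbours, which holds Il10, 5 rose and none fell, as many as adjusted over the list alone (camera, adjusted p = 0.0291, and adjusted p = 0.612 with an estimated correlation). The call was lost without number 1 (adjusted p = 0.0512) and after a correction for gene length and GC content (adjusted p = 0.0811). In place of 5 members, 2, 1 and 1 passed without numbers 1, 2 and 3, 3 after that correction, and 2 when libraries were scaled by totals alone. The members that rose with all numbers included were Il10, Fcmr, at 0.316 ± 0.0922 against 0.0659 ± 0.0175 CPM, Yod1 (0.49), Ikbke (0.35), a kinase gene of interferon signalling, and Srgap2 (0.26). Of 5 Il10-family cytokine and receptor genes tested, Il19 and Il10 rose, and the receptor genes Il10ra (0.12, SE 0.08) and Il20rb (-0.13, SE 0.11) did not pass. Both members that rose also did so adjusted over the list alone. The list was called through Il19, whose reporter defines the groups (camera, adjusted p = 0.0291, and adjusted p = 0.631 with an estimated correlation), and not without Il19 (adjusted p = 0.260, and adjusted p = 0.725 with an estimated correlation).

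Several genes of the LPS response were higher in tdT-positive macrophages. Of 19 LPS effector enzymes and antimicrobial genes, 4 rose and none fell, and 5 rose adjusted over the list alone. F3, which encodes tissue factor, rose by 1.07 (SE 0.15), and Slpi, a protease inhibitor gene, by 0.97 (SE 0.16). Nos2, the inducible nitric oxide synthase gene, was at 1983 ± 933 and 1432 ± 678 CPM (0.48, SE 0.09), and Lcn2, which encodes an iron-siderophore binder, was at 3306 ± 698 and 2092 ± 934 CPM. The list was called with the block (camera, adjusted p = 0.0365) and not without it (adjusted p = 0.381), and not with the block and an estimated correlation (adjusted p = 0.751 with an estimated correlation). The call was lost without number 1 (adjusted p = 0.0517) and without number 4 (adjusted p = 0.194, with 6 members higher and 2 lower), and 1 member passed without number 2 or number 3. The median of the list, 0.08, was -0.00096 when libraries were scaled by totals alone, still with 4 members higher and 0 lower. After the correction for length and GC content it was 0.19, with 6 members higher. Of 20 targets of Nrf2, the transcription factor of the oxidant response, 6 rose and none fell (9 higher and 1 lower adjusted over the list alone). Gclc rose by 0.52, Cat by 0.46, Osgin1 by 0.37 and Slc7a11 by 0.33 (camera, adjusted p = 0.00230 with the block and 0.180 without it, and adjusted p = 0.631 with an estimated correlation and the block). Of these targets 3, 1 and 2 rose without numbers 1, 2 and 3, 2 rose and 1 fell when libraries were scaled by totals alone, and 8 rose and 2 fell after the correction for length and GC content. The chaperone list of the endoplasmic reticulum was called with the block (camera, adjusted p = 0.0443, against 0.108 without it, and adjusted p = 0.612 with an estimated correlation), but Creld2 was its only member of 18 to pass (0.31), and none did adjusted over the list alone. This call was lost without number 1 (adjusted p = 0.116) and without number 3 (adjusted p = 0.0862).

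Cytokine and chemokine genes went both ways. Among 17 inflammatory cytokine genes, Tnfsf15 (0.85) and Il33 (0.85) rose, and Lif (-2.19), Csf1 (-1.51) and Il12b (-0.29) fell (2 higher and 4 lower adjusted over the list alone). Without numbers 1, 2, 3 and 4, 1, 1, 1 and 2 of these cytokine genes rose and 2, 1, 0 and 5 fell. Of 21 chemokine genes, Cxcl5 (0.89) and Cxcl3 (0.66) rose, and Ccl22 (-2.95), Ccl17 (-2.56), Cx3cl1 (-2.25) and Cxcl11 (-0.56) fell (2 higher and 6 lower adjusted over the list alone). Without numbers 1, 2, 3 and 4, 1, 0, 1 and 2 chemokine genes rose and 3, 2, 2 and 8 fell. After the correction for length and GC content 4 rose and 4 fell, and the median turned from -0.10 to 0.09. Without the block, the change of Cxcl5 turned to -0.17 without tdT-positive replicate 4. Camera called neither list (adjusted p = 0.630 and 0.171), but called the chemokines as lower without number 4 (adjusted p = 0.00722, and adjusted p = 0.697 with an estimated correlation). Of 28 type I interferon response genes, 2 rose, Oas2 (0.54) and Oasl2 (0.25), and 1 fell (1 higher adjusted over the list alone; camera, adjusted p = 0.806). Of 18 alternative activation markers, Mrc1, the mannose receptor gene, rose by 0.89 (SE 0.06, adjusted p = 0.00302), and Stab1 (0.44) and Il4ra (0.40) rose, whereas Chil3 and Ccl17 fell (6 higher and 2 lower adjusted over the list alone; camera, adjusted p = 0.0600). Camera called this list as higher without number 2 (adjusted p = 0.0137), without number 3 (0.0302) and after the correction for length and GC content (0.0208), and not with an estimated correlation (0.752, 0.763 and 0.785). Of 21 macrophage identity genes 3 rose and 1 fell, and they included Mertk (0.73) and Maf (0.29), which mark differentiated macrophages and rose, and Timd4 (-1.40), which fell (3 higher and 1 lower adjusted over the list alone). The median of that list was 0.05, or -0.03 when libraries were scaled by totals alone, and camera did not call it (adjusted p = 0.220), but did as higher without number 2 (adjusted p = 0.0326, and adjusted p = 0.752 with an estimated correlation).

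**Figure D3:**
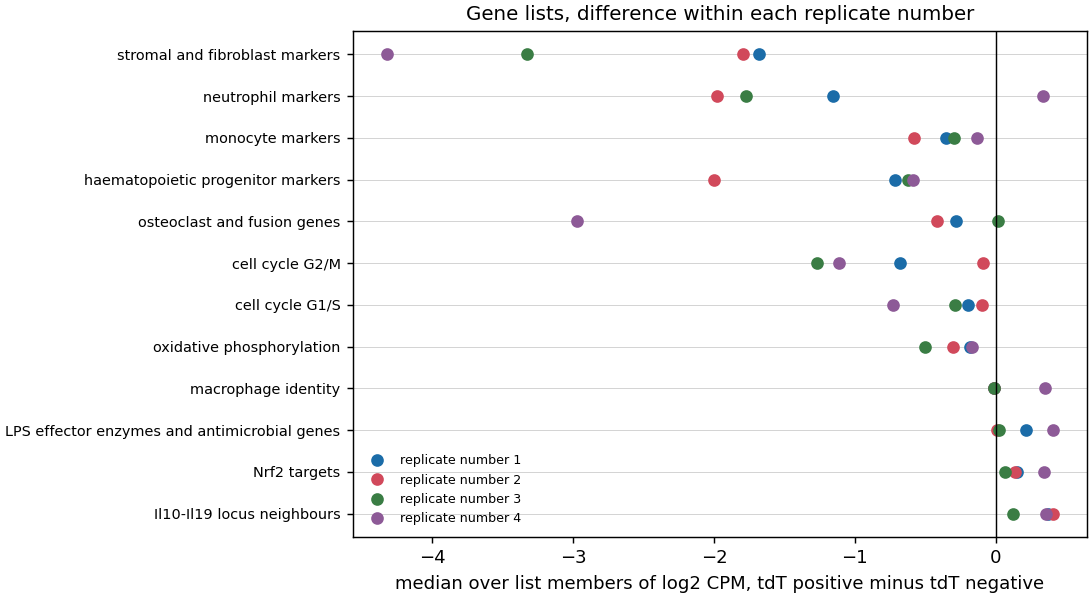
Median over the tested members of 12 gene lists of the log2 CPM difference, tdT positive minus tdT negative, on the horizontal axis, with a point for each of the 4 replicate numbers. The stromal list lies between -4.33 and -1.68 in all 4 numbers, and the neutrophil list lies above 0 in number 4.

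Some genes of cell division were lower in tdT-positive libraries, in which stromal and progenitor markers were lower as well. Of 23 G2/M genes, 7 fell and none rose (11 lower adjusted over the list alone; camera, adjusted p = 5.11e-07, and adjusted p = 0.631 with an estimated correlation). Top2a, which encodes a DNA topoisomerase of dividing cells, was at 5.81 ± 3.03 and 11.1 ± 6.66 CPM (log2 fold change -0.92, SE 0.13), and Kif11, Cdc20 and Nusap1 fell by 1.07 to 1.11. Of 22 G1/S genes, 3 fell: Rrm2 by 1.99, Rrm1 by 0.54 and Mcm6 by 0.49 (5 lower and 1 higher adjusted over the list alone; camera, adjusted p = 0.00228, and adjusted p = 0.631 with an estimated correlation). Without numbers 1, 2, 3 and 4, 1, 1, 0 and 2 G2/M genes and 1, 0, 0 and 3 G1/S genes passed, and 4 G2/M genes did when libraries were scaled by totals alone. With the block and without number 4, camera still called both lists (G2/M with a median of -0.64 and adjusted p = 0.000988, G1/S with adjusted p = 0.0425, and both with adjusted p = 0.697 with an estimated correlation). The median log2 difference of the G2/M list was -0.68, -0.09, -1.27 and -1.11 in numbers 1 to 4. Without the block, its median was -0.17 without tdT-negative replicate 4, and camera then called neither list (adjusted p = 0.182 for G2/M and 0.0530 for G1/S), nor G2/M without tdT-positive replicate 3 (adjusted p = 0.0613).

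Some oxidative phosphorylation genes were lower by small amounts. Of 26 tested, 11 fell and none rose, and 19 fell adjusted over the list alone. The median log2 fold change was -0.28, or -0.15 with 6 members lower after the correction for length and GC content, and Ndufa4, Atp5o, Cox5a and Sdhb fell by 0.47, 0.39, 0.36 and 0.34 (camera, adjusted p = 8.10e-08, and adjusted p = 0.631 with an estimated correlation). The difference was largest in number 3 (median -0.50), where the tdT-positive library had 12.3% of its counts in Rn45s, a ribosomal RNA precursor, against 0.302% to 0.734% in the other 7 libraries. Without number 3 the median was -0.21 and 1 of the 26 members passed, and without numbers 1, 2 and 4, 4, 0 and 18 did. Among 18 genes of the integrated stress response and amino acid supply, Vldlr (-2.81), Phgdh (-2.70), Stc2 (-1.91) and Psat1 (-0.77) fell and Slc7a11 rose (1 higher and 5 lower adjusted over the list alone; camera, adjusted p = 0.0241, and adjusted p = 0.652 with an estimated correlation). Phgdh and Psat1 encode enzymes of serine synthesis, and both were highest in tdT-negative replicate 4 (9.36 and 60.6 CPM). Without number 4 the list was no longer called (adjusted p = 0.0543), and 3, 1 and 1 members passed without numbers 1, 2 and 3.

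Smaller sets of genes changed in further lists that camera did not call. In the p53 target list, Eda2r (-2.69) and Pmaip1 (-0.59) fell and Plk2 (0.38) and Zmat3 (0.26) rose, and among LXR targets Scd1 (-2.01) and Nr1h3 (-0.23) fell and Mylip (0.40) and Lipa (0.27) rose. Among cAMP and CREB targets Nr4a3 (-2.04) and Rgs2 (-0.57) fell, and Ptger2 (0.56), Per1 (0.41) and Ptger4 (0.32) rose. In the lysosome list 1 gene rose and 2 fell, and they included Hexa (-0.26), which fell, and Lipa, which rose. Jun (0.29), Hspa1a (0.56) and Hspa1b (0.32) rose among immediate early and heat shock genes, the heat shock genes being near-identical copies with uncertain counts. Without the block, the changes of Hspa1a, Hspa1b and Plk2 turned to -0.15, -0.48 and -0.0060 without tdT-positive replicate 4. With the block, no LXR, cAMP and CREB, lysosome, or immediate early and heat shock gene passed without number 2 or without number 3. Of the p53 targets, 1 fell without number 2, and 1 rose and 1 fell without number 3. Adjusted over the list alone, 2 p53 targets, 6 LXR targets, 3 cAMP and CREB targets, 1 lysosome gene and 3 immediate early and heat shock genes rose, and 2, 3, 2, 2 and 0 fell, and the camera adjusted p of these lists lay between 0.545 and 0.835. In the remaining 6 lists (NF-kB feedback, Toll-like signalling, interferon-gamma type GTPases, MHC class II, glycolysis and hypoxia, and sterol synthesis) 4 genes rose and 1 fell, and they included Cflar (0.28), Irf8 (0.37) and Cd274 (0.31), which rose, and Traf1 (-0.31), which fell. Adjusted over the list alone these lists had 4 higher and 4 lower members, and camera called none of them in either fit (adjusted p between 0.113 and 0.901 with the block), but called NF-kB feedback without number 2 (adjusted p = 0.0324, and adjusted p = 0.783 with an estimated correlation) and MHC class II without number 4 (adjusted p = 0.0277, and adjusted p = 0.697 with an estimated correlation). Among all 36 lists, camera called 11 without the block and 13 with it, 10 of them in both, and with an estimated correlation it called none in either fit (lowest adjusted p = 0.367 and 0.612).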

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

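All tests of explanations in this part were chosen after the results had been seen, except the count of other splits of the libraries for the fit without the block.

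tdT-positive replicate 3 stood apart from the other tdT-positive libraries in 3 of 10 groups of library measures tested with Dixon's test. Rn45s took 12.3% of its counts (next highest 0.505%), Lars2 took 0.949% (next 0.0801%), and the 10 most abundant genes took 23.3% (next 11.8%). Of 258 groups of 4 CPM values of named genes, 33 (12.8%) had a value that the test flagged. Chance gives about 1 in 20 for independent, normally distributed values. Named genes were picked for their changes and vary together within a library, so 1 in 20 is no benchmark for the 12.8%. Of the 33, 18 were the highest value in tdT-negative replicate 4 and 8 the highest in tdT-positive replicate 4. The test weighs the gap to the next value against the range of the 4 values, so a flagged value can differ little in size. Psat1 in tdT-positive replicate 4, for example, was at 23.0 CPM with the next value at 18.3 CPM.

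In tdT-negative replicate 4 the genes flagged as highest of the tdT-negative libraries included the stromal and matrix genes Col1a1 (857 CPM), Fn1 (732 CPM), Col3a1 (194 CPM) and Wnt5a (21.8 CPM), and the osteoclast genes Ctsk (324 CPM), Atp6v0d2 (110 CPM), Itgb3 (25.8 CPM) and Dcstamp (16.7 CPM). They also included Psat1 (60.6 CPM), Vldlr (14.5 CPM) and Phgdh (9.36 CPM), the cell-cycle genes Rrm1 (33.3 CPM) and Birc5 (3.18 CPM), the cytokine genes Lif (20.6 CPM) and Tnfsf15 (19.9 CPM), and Gclc (49.2 CPM), Hspa1b (19.6 CPM) and Hspa1a (17.0 CPM). In tdT-positive replicate 4 the values flagged as highest were those of Hspa1a (30.8 CPM), Hspa1b (26.5 CPM), Psat1 (23.0 CPM), Itgb3 (1.44 CPM), Ccr7 (1.37 CPM), Dcstamp (0.980 CPM), Kit (0.229 CPM) and Cd34 (0.212 CPM). tdT-positive replicate 2 was flagged as highest for Acta2 (18.9 CPM) and Fermt2 (2.00 CPM) among the tdT-positive libraries, and tdT-positive replicate 3 as lowest for Col6a2 (0.301 CPM). Among the tdT-negative libraries, replicate 3 was flagged as highest for Ptger2 (21.2 CPM) and as lowest for S100a4 (126 CPM) and Mcm6 (43.6 CPM), and replicate 1 as lowest for Rnf183 (5.32 CPM).

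Without the block, 2 of the 35 splits of the 8 libraries into 4 and 4 gave at least the 3 genes of the real split, which is included, so over all splits chance cannot be excluded for that count. The highest other split, with 13 genes, set numbers 1 and 2 against numbers 3 and 4 and left every pair whole, which points to a structure of the samples by number. Among the 8 splits that part all 4 pairs, the real one gave 3 genes and the highest other 0, and 8 splits are too few for a share under 0.05. With the block, 1 of 8 splits within the pairs gave as many genes, the real one with 1998, and the highest other gave 0. Splits within 4 pairs are too few for a share under 0.05.

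Stromal genes and part of the granulocyte genes were lower in the tdT-positive libraries, and 4 of 10 neutrophil markers were higher. Bias by gene length or GC content is argued against for the stromal genes, since 12 of 12 members that passed were still lower after both trends had been removed. A candidate explanation is RNA of stromal cells among the tdT-negative cells: of 20 tested members of another list of stromal genes, 20 were lower, with a median log2 fold change of -2.78, although 14 of them averaged at least 1 CPM in the tdT-positive libraries too and Col1a1 was at 32.4 CPM there. That list was written after the first stromal list had been seen to fall, and tested in the same libraries. Lower expression of such genes by the cells themselves would give the same result, so the list cannot separate it from stromal RNA. For granulocytes and their precursors, 2 of 10 members of another list were lower, Olfm4 (-6.86) and Chil1 (-2.30), and 1 was higher, with a median log2 fold change of 0.05. By the bound first written, 2 of 10 argued against granulocytes, but the bound was revised after that value had been seen. The reason was that 7 of the 10 averaged at least 1 CPM in the tdT-positive libraries. Such a baseline would hide a small share, so the median says little on granulocytes. The other 3 averaged under 1 CPM there and all had negative log2 fold changes. They were Olfm4, Chil1 and Serpinb1a (-2.32, edgeR adjusted p = 0.0594, so not passing). As 3 members are fewer than the 5 that the bound asked for, the presence and absence of granulocytes cannot be told apart. A difference between macrophages with and without Il19 expression stays open for both groups of genes.

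Part of the oxidative phosphorylation and ribosomal protein genes were lower in the tdT-positive libraries, the ribosomal protein genes with uncertain counts because of near-identical copies. Length or GC bias is argued against as the whole cause: the median log2 fold change went from -0.28 to -0.15 (SE 0.03) for oxidative phosphorylation and from -0.38 to -0.23 (SE 0.03) for ribosomal proteins after the correction, and camera still called both, with adjusted p = 0.00507 and 1.76e-11 (adjusted p = 0.567 and 0.194 with an estimated correlation). These SE values are over the genes of each list, counted as independent, and do not measure the spread between libraries. Genes that vary together make them too small. The correction lowered the number of members passing from 11 to 6 and from 44 to 34, so such a bias may account for part of the difference. The RNA of tdT-positive replicate 3 is argued against as the whole cause too, since the median of the oxidative phosphorylation list was -0.21 without number 3 and camera still called it (adjusted p = 2.52e-06, and adjusted p = 0.680 with an estimated correlation), although 1 of 26 members passed. Other differences in RNA quality and a difference between the cells stay open, as untested.

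Il10, Il1f6 and Il1f9 were higher in the tdT-positive libraries. If RNA of other cells had only diluted that of macrophages in the tdT-negative libraries, macrophage genes would be higher by about as much, but the macrophage identity list had a median log2 fold change of 0.045 (SD of its members 0.40), or -0.03 scaled by totals alone, against 0.97 for the smallest of the 3 genes. The RNA of tdT-positive replicate 3 is argued against as well, since without number 3 the highest adjusted p of the 3 genes was 0.0418. A hypothesis that stays open is that macrophages that transcribe Il19 also transcribe more of these 3 genes.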

How the results depend on the processing

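The alternatives with the replicate block other than the block itself, the one without Rn45s and Lars2 counts, the correction for length and GC content, and the Il10 family list without Il19 were chosen after seeing the data. Beyond the values printed with their own setting, 2206 of the recomputed results stayed the same, 254 came to pass and 55 no longer passed. Staying the same means the same direction and side of the threshold, or for counts a similar size. Named genes and lists were compared with the fit without the block, in which 3 of 12610 genes passed. A gene that passed in neither setting thus counts as the same, and this tally does not measure how stable the blocked results are. Of 107 named genes that passed with the block, 71, 38, 33 and 99 still passed without numbers 1, 2, 3 and 4. The log2 fold change of Il19 stayed between 3.81 and 4.16 with any library left out, with an adjusted p of at most 0.00471. The cause was not tested for any change listed here, unless it follows from a threshold, from fewer genes tested or from fewer libraries.

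Without the block, 3 genes passed (1 higher, 2 lower). The count was 921 with the DESeq2 Wald test (327 higher, 594 lower), 216 without a low-count filter (32 and 184), 524 at an adjusted p of 0.1 (154 and 370) and 1998 with the replicate block (1013 and 985), and 1 lower gene was left with library totals only, the stricter filter or an adjusted p of 0.01. With a library left out it ranged from 2 to 456 (1 to 62 higher, 1 to 394 lower), with 456 without tdT-negative replicate 1 and 225 without tdT-negative replicate 4. Of 36 lists, camera called 11, and 0 with an estimated correlation, fry 1, and camera 7 with the stricter filter and 7 (without tdT-negative replicate 4) to 12 with a library left out. With the block, 422 genes were higher with library totals only. At an adjusted p of 0.01, 234 passed (99 higher, 135 lower), at 0.1 3182 (1631 and 1551), and against a 1.5-fold change 296 (24 and 272). With a number left out, the count ranged from 347 to 2535 (94 to 1231 higher, 126 to 1304 lower). With the block, camera called 13 of the 36 lists, and 0 were called with an estimated correlation, 7 by fry, and 10 to 16 with a number left out.

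Directions turned without the block as follows. Log2 fold changes ranged, with a library left out, from -0.30 to 0.77 for Pf4 (-0.050 with library totals only), -0.043 to 0.049 for Blnk (0.0025 without a filter), -0.055 to 0.30 for Il7r, -0.20 to 0.45 for Vcan, -0.18 to 0.064 for Cd48, -0.03 to 0.23 for Il10ra and -0.37 to 0.12 for Il20rb. They turned without tdT-positive replicate 4 for Cxcl5 (-0.17 to 1.55), Hspa1a (-0.15 to 1.28), Hspa1b (-0.48 to 1.09) and Plk2 (-0.0060 to 0.79). The direction of camera, which can differ from the sign of the median, turned for lists with medians from -0.27 to 0.22 (inflammatory cytokines), -0.18 to 0.20 (type I interferon), -0.26 to 0.20 (cAMP and CREB), 0.014 to 0.19 (LXR), 0.0027 to 0.066 (lysosome), -0.049 to 0.12 (macrophage identity), -0.026 to 0.13 (p53, 0.055 with the block and 0.091 with the stricter filter) and -0.10 to 0.11 (immediate early and heat shock genes, -0.031 by fry, -0.010 with the block, -0.021 with the stricter filter and -0.036 with DESeq2 factors). None of these lists was called.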

Other observations

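The families of genes in this part, and all tests reported here, were chosen after the data had been seen, and all values are from the fit with the replicate block.

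Further families of genes changed between tdT-positive and tdT-negative libraries. Of 27 collagen genes tested, 17 fell and none rose, with a median log2 fold change of -2.69 (camera, adjusted p = 5.09e-08 over 7 families, and adjusted p = 0.269 with an estimated correlation). Without number 3, 1 collagen gene passed, with a median of -2.47. They included Col4a1 (-2.51, SE 0.36), of basement membranes, Col2a1 (-3.27, SE 0.45), of cartilage, and Col12a1 (-3.09, SE 0.52). Matrix metalloproteinase genes went both ways: of 14 tested, 6 rose and 2 fell (camera, adjusted p = 0.304), and 4 rose and 0 fell without number 3. Mmp3 rose by 1.75 (SE 0.30), Mmp27 by 1.04, Mmp10 by 0.90, Mmp13 by 0.89 (SE 0.08, 670 CPM in tdT-negative libraries) and Mmp12, the macrophage elastase gene, by 0.62, whereas Mmp2 (-2.30) and Mmp23 (-2.79) fell. Of 7 interleukin-1 family ligand genes, Il1f9, Il1f6 and Il33 rose and the other 4 did not pass (camera, adjusted p = 0.0210, and adjusted p = 0.340 with an estimated correlation), and 2 rose without number 3. Il1a and Il1b, among those 4, had log2 fold changes of -0.06 (SE 0.10) and -0.12 (SE 0.13).

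All 5 Kmt2 genes, a family grouped by its symbol, which is short for lysine methyltransferase, rose: Kmt2d by 0.81, Kmt2a by 0.77, Kmt2c by 0.52, Kmt2b by 0.50 and Kmt2e by 0.42 (camera, adjusted p = 1.23e-05, and adjusted p = 0.269 with an estimated correlation). Without number 3, 3 of the 5 passed. Of 10 transcripts known to be retained in the nucleus, Malat1 (0.91), Leng8 (0.89), Neat1 (0.88) and Srrm2 (0.32) rose and none fell (camera, adjusted p = 0.00215, and adjusted p = 0.269 with an estimated correlation). After a correction for length and GC content 2 rose (camera, adjusted p = 0.00609, and adjusted p = 0.194 with an estimated correlation). Of 74 ribosomal protein genes, 44 fell and none rose (camera, adjusted p = 4.20e-18, and adjusted p = 0.269 with an estimated correlation), and 6 of 73 did without number 3. None of 6 C/EBP genes passed (camera, adjusted p = 0.564). Shares by transcript length were counted without a test: of the fifth of genes with the longest transcripts 18.2% were higher and 8.37% lower, and of the fifth with the shortest 1.82% were higher and 10.3% lower. The Spearman correlation of the log2 difference with length was 0.108, 0.332, 0.326 and -0.0431 in numbers 1 to 4, so it was weak in number 1 and turned in number 4. After the correction for length and GC content these shares were 8.29%, 10.98%, 4.04% and 5.31%, and the 5 Kmt2 genes still rose, with a median of 0.32 in place of 0.52.

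Of 18 tested genes within 1 Mb of Il19 on chromosome 1, 5 were higher in the tdT-positive libraries, the same 5 as in the list of neighbours in the report, and Cd55 (-0.46) was lower. Of 9103 windows around other tested genes, 0.659% had as high a share (median 8.33%). This count was made after the 5 genes had been seen to rise, and overlapping windows are not independent, so it is no separate evidence on the region.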
